A study of Homo sapiens with 8 samples.

How the data were processed

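RNA was measured by sequencing in MRC5_VA cells, a transformed line of human lung fibroblasts, in a chromatin fraction and a cytoplasm fraction. Cells had no UV, or 10 J/m2 of UV-C followed by 30 min, 3 h or 24 h of recovery. That makes 4 conditions, 2 fractions and 8 libraries, with 1 library per fraction and condition. Per the labels' protocols, total RNA of each fraction was taken up in Trizol and libraries were built with a NEBNext Ultra RNA kit. Whether RNA with a poly(A) tail was selected, or ribosomal RNA removed, is not given in the sources used here. Whether the counting used the strand is also not given in the sources used here.

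The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the depth of the library), per the file headers, with 1 column per library and 1 line per transcript. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and genome build hg38 were used, with no role given for either tool. How the FPKM of a transcript was estimated, which annotation was used and whether low transcripts were removed are not given in the sources used here. The table listed 81130 transcripts, of which 62595 had an Ensembl identifier, 6602 were assembled models named LNC and 11933 were assembled models named TUCP. No scaling between libraries beyond FPKM is recorded, and every column belonged to a library of the series.

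Transcript values were summed per gene symbol, or per gene identifier for assembled models, to give 33945 genes. Of these, 16380 were protein-coding. Coordinates and spans came from GENCODE release 29 on hg38, counted from 1, and were found for 16360 of the protein-coding genes. Gene symbols that a spreadsheet had turned into dates (25 genes) were restored from the Ensembl identifier. A gene was treated as uncertain where its exons overlap those of another listed gene, since fragments of the pair cannot be told apart without strand or model information. Read-through models that join neighbouring genes, near-identical paralogs such as the histone genes and HSPA1A with HSPA1B, and genes with many processed pseudogenes such as those of ribosomal proteins and actins are uncertain for the same reason. Symbols are those of the table. Genes of the Y chromosome and XIST are not reported.

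No counts came with the table. In 8380 genes with 1 listed transcript, FPKM times length fell on multiples of a step per library, and the step gave an estimate of depth. That estimate was 42.7, 40.6, 36.5 and 39.8 M (mega) fragments for chromatin without UV and at 30 min, 3 h and 24 h. For cytoplasm it was 83.2, 52.8, 53.9 and 51.8 M. Between 29.4% and 38.9% of low values lay within 0.02 of a whole multiple, so whole fragments were not recovered and the values were not treated as counts. The estimated fragments were used for counting intervals alone. A fold for a single gene is the ratio of its FPKM values, and its 95% interval is an exact binomial (Clopper-Pearson) interval for the ratio of estimated fragments. Both cover counting error only. In a transcript of 1 kb, 3 fragments correspond to an FPKM of 0.0703 to 0.0823 in chromatin and 0.0361 to 0.058 in cytoplasm. An exact 0 can be a failed estimate and is given as listed at 0, with no fold.

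All changes are differences in log2(FPKM + 1), which understates the change of low genes. Each UV library was set against the library without UV of the same fraction, 6 comparisons in all. With 1 library per group there was no test and no p-value. A size rule was used in its place: FPKM of at least 1 in 1 of the pair of libraries and a difference of at least 1 in log2(FPKM + 1), here called at least 2-fold. Genes past that rule are said to have risen or fallen. Chromatin was compared with cytoplasm over all 8 libraries with limma 3.58.1 (R 4.3.3, trend in eBayes) in genes with FPKM of at least 1 in 2 or more libraries. The condition was a block of 4 levels. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and at least 2-fold. The 4 conditions serve as 4 pairs, so the error is the spread of the fraction difference over conditions, not over repeat cultures.

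Gene lists (23) were written before the data were examined: p53 targets, immediate-early genes, nucleotide excision repair, NF-kB and inflammatory genes, interferon-stimulated genes, integrated stress and unfolded protein response, heat shock, G2/M and mitosis, G1/S and DNA replication, extracellular matrix and fibroblast genes, cholesterol synthesis, RNA polymerase II subunits, RNA polymerase II elongation factors, SR proteins and splicing factors, nuclear lncRNAs, snoRNA host genes, abundant cytoplasmic mRNAs, mitochondrially encoded genes, ribosomal proteins, replication histones, and markers of epithelial, endothelial and leukocyte cells. Each list's median change has a 95% interval over its members, and a percentile among 10000 random lists of the same size matched on mean expression. A second percentile also matched the span of the genes. Percentiles describe these libraries and are not tests. A median was singled out where its percentile lay below 2.5 or above 97.5. Protein-coding genes were also grouped by span on the genome, with bounds at 10, 30 and 100 kb. The genes named were fixed by rule before the data were examined. For each UV comparison they are the 5 largest rises and the 5 largest falls among protein-coding and lncRNA genes with FPKM of at least 5 in 1 library of the pair. For the fractions they are the 10 largest differences in each direction, with a mean FPKM of at least 5 and the same direction in all 4 conditions. Up to 4 members of each list with the largest changes were added. Genes named outside the rule are said to have been chosen after their values were seen.

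Alternatives covered the pseudocount (0.1 and 5), the FPKM filter (5, or none), scaling by median-of-ratios size factors, rescaling over protein-coding genes without mitochondrial genes, protein-coding genes alone, a size rule of 1.5-fold or 3-fold, counting intervals, exonic length in place of span, the fit without the block, and leaving out each condition. Added after seeing the data were the removal of genes with overlapping exons, subtraction of cytoplasm carried over into chromatin, restriction to genes higher in chromatin without UV or in libraries outside the comparison (24 h, or 3 h for the change at 24 h), the fraction fit without the 30 min and 3 h conditions, list medians rescaled over protein-coding genes, and other settings for the genes shared by the fractions. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated data. In libraries simulated for the 3 h chromatin comparison (13778 genes), the size rule called none of 13578 unchanged genes, 0 of 50 changed 1.5-fold, 44 of 50 changed 3-fold and 48 of 50 changed 8-fold. Those libraries held counting noise alone, with no spread between cultures, preparations or transcript assignments. The lack of calls among unchanged genes therefore says nothing about false calls from such spread in the real pairs. In simulated data for chromatin against cytoplasm (17417 genes), limma recovered 26 of 50 genes planted at log2 1.5, 41 of 50 at 2 and 48 of 50 at 4, with 4 calls among 17217 unchanged genes.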

Results

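RNA levels were measured by RNA sequencing in MRC5_VA cells, human lung fibroblasts transformed with SV40. RNA came from a chromatin fraction, which holds RNA still attached to or retained on chromatin, and from a cytoplasm fraction, which holds exported RNA. Mitochondrially encoded RNA and some nuclear RNA, such as MALAT1, were also found in the cytoplasm fraction. UV-C light of 10 J/m2, a source of bulky DNA lesions that block RNA polymerases, was followed by 30 min, 3 h or 24 h of recovery, and untreated cells gave the library without UV. Each fraction and condition had 1 library, so no comparison with the cells without UV has a replicate check. Depth was estimated at 36.5 to 42.7 M (mega) fragments in chromatin and 51.8 to 83.2 M in cytoplasm, the highest being cytoplasm without UV. Levels are FPKM values, and changes are differences in log2(FPKM + 1).

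The makeup of the libraries differed between conditions. MALAT1, a nuclear long non-coding RNA, took 24.98% of all chromatin FPKM without UV, 16.0% at 30 min, 18.5% at 3 h and 19.8% at 24 h. Its estimated fragments at 30 min were 0.178 to 0.179 of those without UV, against 0.693 in FPKM, so its level depends on which of its transcripts the fragments were assigned to. Replication histone mRNAs took 48.03% of cytoplasm FPKM without UV and 33.5%, 20.4% and 26.1% at 30 min, 3 h and 24 h. Mitochondrially encoded RNAs took 1.63% of cytoplasm FPKM without UV, 6.95% at 30 min, 2.97% at 3 h and 2.35% at 24 h. In 198 mRNAs abundant in cytoplasm (FPKM of at least 200), the median chromatin to cytoplasm ratio was 7.13% without UV. It was 15.5% at 30 min, 14.5% at 3 h and 6.15% at 24 h. The chromatin libraries of 30 min and 3 h thus stood apart, and UV cannot be separated here from a difference between preparations.

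The first comparison asked which RNAs lay on chromatin and which in cytoplasm, over all 4 conditions. Nuclear lncRNAs and part of the splicing factor mRNAs were higher in chromatin, while histone, ribosomal protein and other housekeeping mRNAs were higher in cytoplasm. NEAT1 (ENSG00000245532, chromosome 11, 65422774 to 65445540), the scaffold RNA of paraspeckles, was at 708.1 ± 274.4 FPKM in chromatin and 4.40 ± 1.25 in cytoplasm (mean ± SD, n = 4 conditions). MALAT1 was at 58965 ± 8980 FPKM in chromatin and 784.7 ± 91.1 in cytoplasm. HIST1H4J, a histone H4 gene of the cluster on chromosome 6, was at 21.5 ± 5.75 FPKM in chromatin and 12818 ± 6652 in cytoplasm. RPL27, a protein of the large ribosomal subunit, was at 29.4 ± 12.4 FPKM in chromatin and 1222 ± 233 in cytoplasm.

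Of 17417 genes tested with limma, 6832 were higher in chromatin and 2871 in cytoplasm at an adjusted p below 0.05 and at least 2-fold. The differences in log2(FPKM + 1) were 6.99 for NEAT1 (SE 0.30, limma adjusted p = 7.51e-11), 6.22 for MALAT1 (SE 1.04, adjusted p = 5.93e-05) and -9.06 for HIST1H4J (SE 0.46, adjusted p = 4.88e-10). NEAT1 and MALAT1 were higher in chromatin, and HIST1H4J in cytoplasm, in 4 of 4 conditions. After them in chromatin came IGFN1 (5.56), NPIPB4 (4.85), ANKRD36C (4.75), LY6G5B (4.71), the splicing kinase PRPF4B (4.61), GOLGA8B (4.59), NPIPB5 (4.43) and BOD1L1 (4.37). NPIPB4, NPIPB5, ANKRD36C and GOLGA8B have close paralogs and LY6G5B overlaps another gene, so these values are uncertain. The 10 largest differences towards cytoplasm were all replication histones, from HIST1H4J to HIST1H2AI (-7.90). Histone genes are near-identical, so values of single members are uncertain.

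Among the fixed lists, 8 of 10 nuclear lncRNAs were higher in chromatin and 1 in cytoplasm (median 2.94, 95% interval -0.19 to 6.22), with TUG1 at 98.6 FPKM in chromatin and 7.53 in cytoplasm. SR proteins and splicing factors followed with 10 of 20 higher in chromatin and 2 in cytoplasm (median 1.25, -0.09 to 2.67), among them SRSF5 (657.3 and 37.7 FPKM) and RSRC2 (99.2 and 4.98 FPKM). These medians exceeded those of all 10000 random lists. All 25 abundant cytoplasmic mRNAs were higher in cytoplasm (median -3.34), such as galectin-1 LGALS1 (25.2 FPKM in chromatin, 965.7 in cytoplasm) and beta-actin ACTB (257.0 and 6036 FPKM). So were 75 of 79 ribosomal proteins (median -3.50) and 64 of 65 replication histones (median -7.17), with 1 histone higher in chromatin. RNA polymerase II subunits (9 of 12 higher in cytoplasm, 1 in chromatin, median -2.04) lay on the same side, with POLR2G at 26.1 and 128.5 FPKM.

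The other lists are given as members higher in chromatin and in cytoplasm out of those measured. Counts were 3 and 6 of 26 p53 targets (median -0.16), 3 and 7 of 27 immediate-early genes (-0.51), 6 and 9 of 32 nucleotide excision repair genes (-0.11), and 3 and 4 of 17 NF-kB and inflammatory genes (-0.60, but positive with an FPKM filter of 5). They were 5 and 3 of 18 interferon-stimulated genes (0.55), 1 and 9 of 20 integrated stress and unfolded protein response genes (-0.82), 0 and 9 of 14 heat shock genes (-1.34), and 6 and 9 of 24 G2/M genes (-0.36). They were 1 and 7 of 25 G1/S genes (-0.66), 6 and 5 of 23 extracellular matrix genes (-0.06), 2 and 10 of 18 cholesterol synthesis genes (-1.22), 9 and 4 of 24 elongation factors (0.39), 6 and 3 of 16 snoRNA host genes (0.40) and 1 and 9 of 13 mitochondrially encoded genes (-1.59). Adjusted over the list alone, every list's counts were the same as over all genes tested. ERCC6, the transcription-coupled repair factor, was at 42.1 FPKM in chromatin and 6.27 in cytoplasm (2.54, SE 0.23, limma adjusted p = 1.40e-07), and the mitotic genes MKI67 (3.65) and CENPF (3.62) were also higher in chromatin. The small heat shock protein gene HSPB1 (6.61 and 329.4 FPKM) was higher in cytoplasm. Of the marker lists, 2 of 3 measured epithelial genes, the keratins KRT18 (57.9 and 810.3 FPKM) and KRT8 (11.7 and 34.97 FPKM), whose exons overlap other genes, were higher in cytoplasm (median -1.50). Only 1 endothelial and 2 leukocyte markers of 10 each could be measured.

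The balance between the fractions depends on scaling, since FPKM is relative to each library's own total. Rescaling over protein-coding genes moved the median of all genes tested from 0.67 to 1.70 and the split to 18085 genes higher in chromatin and 869 in cytoplasm. It also raised the values against the fixed filter and pseudocount of 1, more in chromatin, so 24855 genes were tested against 17417. The medians of all genes therefore cover different sets, and scaling was not the only change. List medians were affected as well. Medians below 0 then turned positive in every list but the RNA polymerase II subunits, abundant cytoplasmic mRNAs, mitochondrially encoded genes (-0.003), ribosomal proteins and replication histones. Within protein-coding genes alone the split was 2820 to 2760.

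**Figure D1:**
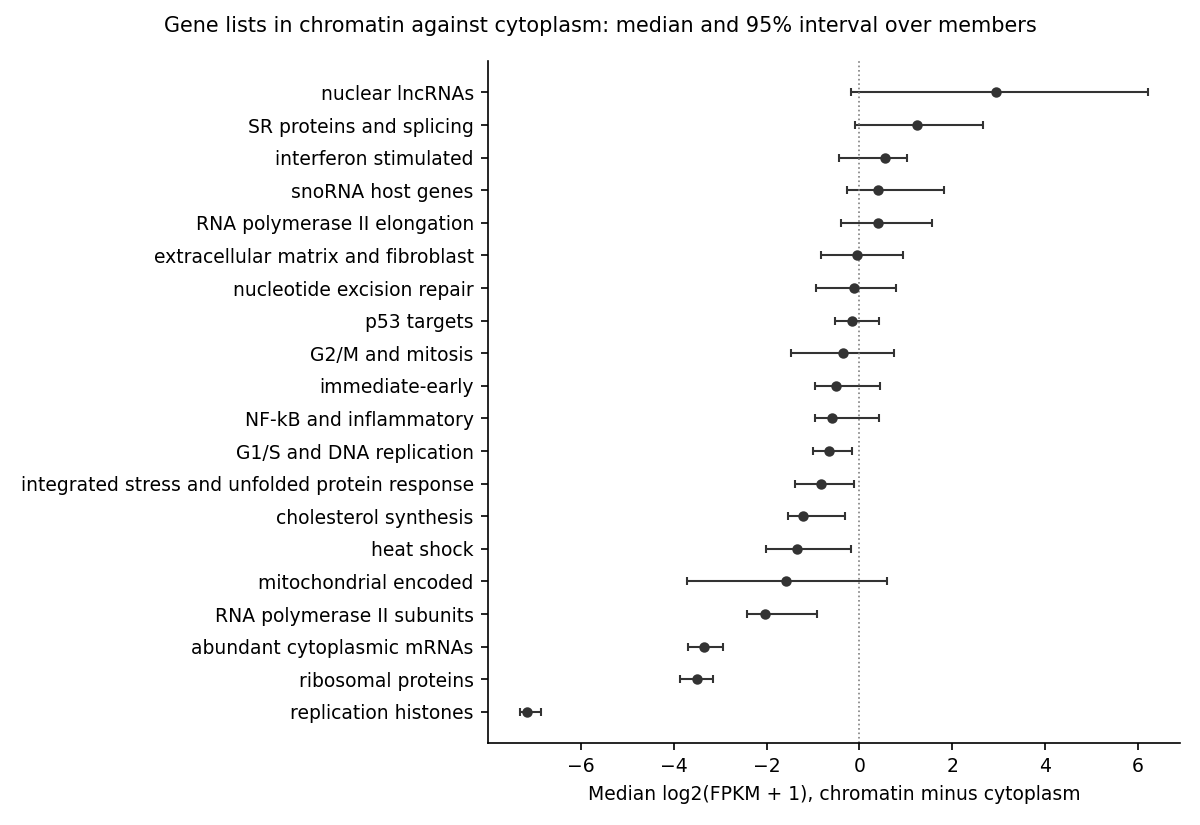
Median difference in log2(FPKM + 1) between chromatin and cytoplasm for each fixed gene list over 4 conditions, with points for medians and bars for 95% intervals over list members. Nuclear lncRNAs lie highest at 2.94 and replication histones lowest at -7.17, and rescaling over protein-coding genes turns most of the negative medians positive.

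The next comparisons asked how RNA on chromatin changed with recovery from UV. At 30 min, most immediate-early and ribosomal protein genes were higher on chromatin. FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230), a subunit of the AP-1 transcription factor, rose from 0.709 to 25.3 FPKM, a fold of 35.6 (95% interval 21.1 to 39.8). Its relative FOSB rose from 0.31 to 11.9 FPKM and IER2, another early-response gene, from 2.15 to 18.4 FPKM. PPP1R15A (GADD34), which directs dephosphorylation of the translation factor eIF2 alpha, rose from 32.5 to 167.9 FPKM and was chosen after its values were seen. The stress-response transcription factor ATF4 rose from 48.8 to 181.9 FPKM. TXNIP, a regulator of thioredoxin and glucose uptake, rose from 1.07 to 22.3 FPKM.

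In all, 1688 genes rose and 772 fell in chromatin at 30 min, of 17058 measured. Of 28 immediate-early genes measured, 18 rose and 1 fell (median 1.48, 95% interval 0.81 to 2.33), a median above all random lists matched on expression or also on span. Ribosomal proteins rose in 74 of 79 (median 1.52), led by RPS15 (4.52 to 40.3 FPKM). Abundant cytoplasmic mRNAs rose in 20 of 25 (median 1.45), with the ferritin chain FTL going from 23.3 to 137.2 FPKM. The snoRNA host genes, whose introns encode small nucleolar RNAs, rose in 10 of 16 (median 1.32), and SNHG15 went from 14.5 to 57.7 FPKM. Integrated stress and unfolded protein response genes rose in 7 of 20 (median 0.89) and NF-kB and inflammatory genes in 6 of 16 (median 0.83). In the latter, NFKBIZ went from 14.2 to 45.1 FPKM and NFKBIA, the inhibitor of NF-kB, from 7.38 to 19.9. Heat shock genes rose in 5 of 14 (median 0.72), with HSPA1A at 9.10 FPKM without UV and 54.2 at 30 min, a value uncertain because of its paralog HSPA1B. RNA polymerase II subunits rose in 6 of 12 (median 0.90), G1/S genes in 5 of 25 (0.58), p53 targets in 7 of 26 (0.57) and extracellular matrix genes in 9 of 22 (0.69). TGFBI (2.74 to 13.5 FPKM) and COL6A1 (13.8 to 41.7) led the last group. Matched also on span, the medians of RNA polymerase II subunits (percentile 94.4), G1/S genes (90.4), p53 targets (90.7), heat shock genes (89.8) and replication histones (61.3) lay within the middle 95% of random lists, while those of the other lists in this paragraph lay beyond it. Cholesterol synthesis genes had 0 of 18 past the rule and a median of -0.01.

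Of the 5 largest rises and 5 largest falls, 5 were in genes that share exons with a neighbour and are uncertain for that reason. These are RSC1A1, PPAN-P2RY11 (listed at 0 without UV, 11.8 FPKM at 30 min), CHMP4A, BIVM-ERCC5 (7.41 FPKM, then listed at 0) and BCL2L2. The intronic transcripts ACAP2-IT1 (22.4 to 0.779 FPKM) and ASAP1-IT2 (14.5 to 2.26 FPKM) fell, but their fragments may not be told apart from unspliced RNA of the genes that hold them.

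At 3 h, the chromatin changes were more numerous, with 3940 genes that rose and 1741 that fell of 18055. HEXIM1 (chromosome 17, 45148502 to 45152101), an inhibitor of the elongation kinase P-TEFb, rose from 8.44 to 177.5 FPKM, though its exons overlap another gene. ELOF1 (chromosome 19, 11551147 to 11559236), an elongation factor with a part in transcription-coupled repair, rose from 6.92 to 68.9 FPKM, and CDK9, the P-TEFb kinase, from 11.8 to 45.6. Of the 24 elongation factors listed, 6 rose and 3 fell (median 0.58, percentile 88.7), with ELL2 (68.3 to 17.5 FPKM) and the P-TEFb cyclin CCNT2 (44.5 to 21.5) among the falls. RNA polymerase II subunits rose in 8 of 12 (median 1.39, 95% interval 0.83 to 1.98), including POLR2D (5.34 to 21.3 FPKM). The ribosomal protein RPLP0 rose from 94.8 to 808.4 FPKM, and 68 of 79 genes of its list rose (median 1.52). The microtubule-binding ubiquitin ligase MID1 (388.4 kb) fell from 80.6 to 8.49 FPKM. SRSF4 (62.7 to 22.8 FPKM) and CENPE (47.5 to 20.4 FPKM) also fell.

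Extracellular matrix genes rose in 12 of 23 at 3 h in chromatin (median 1.01), with COL6A1 at 76.8 FPKM and COL6A2 at 40.0. Abundant cytoplasmic mRNAs rose in 20 of 25 (median 1.47), G1/S genes in 10 of 25 (0.89), and NF-kB genes in 6 of 12 (0.99). Immediate-early genes rose in 12 of 25 and fell in 1 (median 0.95). FOS, looked up after its 30 min value was seen, was at 2.12 FPKM, against 0.709 without UV, and missed the rule by its change of 0.87. FOSB (5.95 FPKM) and IER2 (13.6) rose. Among p53 targets 10 of 25 rose (median 0.62), with AEN going from 5.64 to 34.0 FPKM and CDKN1A (p21) from 1.54 to 8.93. The snoRNA host genes rose in 7 of 16 (0.93) and SR proteins in 5 of 20 with 1 lower (0.66). Heat shock genes rose in 6 of 14 (0.89), interferon-stimulated genes in 4 of 18 with 1 lower (0.58), and integrated stress genes in 6 of 19 (0.59). G2/M genes had 2 of 24 higher and 1 lower, and a median of 0.13 that turned to -0.07 and -0.25 under the other scalings. Nucleotide excision repair genes had 7 of 32 higher and 1 lower. Their median was 0.25 (percentile 48.3), or 0.06 and -0.12 under those scalings. Matched also on span, the medians at 3 h of ribosomal proteins, abundant cytoplasmic mRNAs and extracellular matrix genes lay above the middle 95% of random lists. Those of immediate-early genes (percentile 42.7), p53 targets (56.6), NF-kB genes (82.8), G1/S genes (83.2), snoRNA host genes (21.2) and RNA polymerase II subunits (96.2) lay within it, and those of G2/M genes (1.99), replication histones (1.75) and cholesterol synthesis genes (0.53) below it. PPAN-P2RY11, HNRNPH2 and RPL17-C18orf32, among the 5 largest rises, and CHMP4A and NPIPA2, among the falls, are uncertain through shared exons or paralogs.

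At 24 h on chromatin, p53 targets stood out, with 12 of 26 that rose and none that fell (median 0.97, 95% interval 0.70 to 1.23, above all random lists). Whether p53 itself drove these rises in cells transformed with SV40 was not tested. BTG2, an antiproliferative p53 target, rose 8.88-fold (7.34 to 10.9). CDKN1A (chromosome 6, 36676460 to 36687339), the p21 inhibitor of cyclin-dependent kinases, rose from 1.54 to 8.09 FPKM (fold 5.25, 4.76 to 7.01). MDM2, the ubiquitin ligase that restrains p53, rose from 12.5 to 44.7 FPKM, with overlapping exons, and TP53INP1 from 3.09 to 12.9. Interferon-stimulated genes rose in 5 of 17 (median 0.62), such as IFIT3 (3.19 to 12.1 FPKM) and ISG20 (0.904 to 8.50 FPKM). Mitochondrially encoded RNAs fell in 6 of 13 (median -0.95, -1.33 to -0.71), led by MT-ND6 (945.8 to 136.7 FPKM).

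In total 1459 genes rose and 844 fell of 17790 in chromatin at 24 h. Ribosomal proteins rose in 2 of 79 by this time (median 0.54). Immediate-early genes rose in 9 of 26 (median 0.61), while the growth regulator MYC fell from 7.48 to 1.98 FPKM. RNA polymerase II subunits rose in 2 of 12 (0.68, POLR2A 32.2 to 81.5 FPKM) and elongation factors in 3 of 24 (0.47). Of 21 extracellular matrix genes 2 fell, COL5A1 (86.8 to 41.5 FPKM) among them, and the median was -0.38 (-0.57 to 0.26), below all random lists. Cholesterol synthesis genes had none past the rule (median -0.12, percentile 1.13). Among 3 leukocyte markers 2 rose (median 1.89): CD14 from 0.477 to 6.59 FPKM, and CD79A, listed at 0 without UV, to 2.70. No endothelial marker was measured. The zinc finger gene ZNF182 rose from 1.47 to 19.3 FPKM. HNRNPH2, GNAL and APOE among the largest rises, and CHMP4A, BIVM-ERCC5, PTPRG and KCNH7 among the falls, share exons with another gene.

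The balance of rises and falls on chromatin depends on scaling. After median-of-ratios scaling the median change of all genes moved from 0.12 to -0.07 at 30 min, from 0.20 to 0.01 at 3 h and from 0.19 to 0.05 at 24 h. The counts of genes higher and lower became 1112 and 1258, 3094 and 2557, and 1165 and 1147. Rescaled over protein-coding genes, they were 2330 and 3951, 5175 and 6234, and 4373 and 2824. Median changes of all genes tested were then -0.18, -0.12 and 0.14. This rescaling let 24654, 25818 and 26576 genes past the filter, against 17058, 18055 and 17790, so the counts do not reflect scaling alone. Of the chromatin lists given, the medians of G2/M genes, replication histones, nucleotide excision repair genes and cholesterol synthesis genes (0.11) at 3 h changed sign under scaling and the others did not.

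In cytoplasm at 30 min, mitochondrially encoded RNAs were the clearest group, and all 13 rose (median 2.29, 95% interval 1.999 to 3.004). Their median in cytoplasm was 0.59 at 3 h and -0.04 at 24 h, and on chromatin at 30 min it was 0.27. The 30 min value rests on 1 library, so UV cannot be separated here from a difference between preparations in the mitochondrial RNA they held. MT-ND2, a subunit of respiratory complex I, rose from 267.96 to 2213 FPKM (fold 8.26, 8.14 to 8.37), and MT-ND1 from 549.9 to 3297. IER2 rose from 4.68 to 29.5 FPKM, FOS from 2.48 to 9.74 and PPP1R15A from 39.8 to 97.8. Replication histone mRNAs fell in 14 of 64 (median -0.67, -0.80 to -0.56), as in HIST1H2BJ (5179 to 1901 FPKM). Cholesterol synthesis genes fell in 4 of 18 (median -0.54), among them MSMO1 (54.4 to 21.5 FPKM) and HMGCS1 (31.2 to 12.4 FPKM), both sterol pathway enzymes.

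Over all genes in cytoplasm at 30 min, 336 rose and 196 fell of 12137. The snoRNA host genes rose in 7 of 16 (median 0.83), with SNHG5 going from 33.4 to 81.6 FPKM. Immediate-early genes rose in 5 of 26 and 1 fell, namely MYC (36.2 to 9.96 FPKM, median of the list 0.35). Interferon-stimulated genes (median -0.43), heat shock genes (-0.32) and G2/M genes (-0.23) had none past the rule, and their medians lay at percentiles 0, 0.19 and 0.16. Ribosomal proteins had 1 of 79 higher and a median of 0.45, and RNA polymerase II subunits none of 12 and a median of 0.42. Epithelial markers had none of 3 past the rule (median -0.53). TGIF2-C20orf24, TRAPPC5, THAP7-AS1, HSPE1-MOB4 (listed at 0 after UV), CHMP4A and SLCO1B3 had the largest changes and share exons with neighbours. PCLO fell from 9.71 to 1.12 FPKM, but its estimated fragments gave a ratio of 0.858 to 1.003, so the change lies in which transcript length was listed.

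At 3 h, the histone mRNAs in cytoplasm had fallen in 57 of 64 (median -1.68, 95% interval -1.80 to -1.60), below all random lists. HIST1H1D (ENSG00000124575, chromosome 6, 26234268 to 26234933), a linker histone gene, fell from 1934 to 279.04 FPKM, 6.93-fold lower (6.79 to 7.08). On chromatin at 3 h the same list had 2 of 60 higher, none lower and a median of 0.13, which turned to -0.05 and -0.23 under the other scalings. Cholesterol synthesis genes fell in 5 of 18 in cytoplasm (median -0.70), including the sterol sensor partner INSIG1 (56.4 to 22.5 FPKM). The early gene KLF10 rose from 13.3 to 49.0 FPKM and ATF4 from 43.9 to 108.7. RNA polymerase II subunits rose in 5 of 12 (median 0.82), with POLR2H going from 33.4 to 90.3 FPKM.

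In all 460 genes rose and 308 fell in cytoplasm at 3 h, of 11812. Ribosomal proteins rose in 8 of 79 (median 0.61), snoRNA host genes in 5 of 16 (0.61) and immediate-early genes in 5 of 26 with 1 lower (0.46). Interferon-stimulated genes had 1 higher and 1 lower of 16 and a median of -0.40. Matched also on span, the medians at 3 h of immediate-early genes (percentile 80.6) and snoRNA host genes (93.95) lay within the middle 95% of random lists, as did immediate-early genes at 30 min (93.5). Heat shock genes had none past the rule and a median of -0.30, which became 0.07 when rescaled over protein-coding genes. G2/M genes likewise had none (median -0.35). Nucleotide excision repair genes had none higher and 1 lower of 32 (0.22), the lower one being ERCC5, which shares exons with BIVM-ERCC5. The glycosylation chaperone C1GALT1C1 fell from 19.2 to 1.27 FPKM. TMEM189-UBE2V1, BORCS8-MEF2B, THAP7-AS1, TGIF2-C20orf24, TREX2, BOLA2, HSPE1-MOB4 and SLCO1B3 complete the largest changes and share exons with other genes.

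At 24 h, the median of extracellular matrix mRNAs was lower in cytoplasm and that of p53 targets higher. Of 21 matrix genes 13 fell and none rose (median -1.22, 95% interval -1.77 to -0.12). Fibrillin FBN1 fell from 21.0 to 4.03 FPKM, and the fibrillar collagens COL5A2 (chromosome 2, 189031896 to 189225312) from 41.9 to 8.89 FPKM (4.71-fold lower, 4.54 to 4.89) and COL3A1 from 35.4 to 8.35. Among p53 targets 9 of 27 rose (median 0.62), with MDM2 going from 7.50 to 46.7 FPKM, the secreted factor GDF15 from 1.26 to 8.71, BTG2 from 0.86 to 6.15 and GADD45A from 9.41 to 35.4. Ribosomal proteins rose in 48 of 79 (median 1.10, 0.997 to 1.18), for example RPS12 (220.8 to 743.5 FPKM).

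Counts in cytoplasm at 24 h were 594 rises and 522 falls of 11787 genes. RNA polymerase II subunits rose in 8 of 12 (median 1.15), with POLR2K going from 47.6 to 143.1 FPKM. Histone mRNAs were still lower in 33 of 64 (median -1.004), as were cholesterol synthesis genes in 2 of 18 (median -0.47), INSIG1 being at 21.4 FPKM. Interferon-stimulated genes rose in 4 of 18 (0.26), including IFIT3 (5.88 to 17.3 FPKM), and snoRNA host genes in 6 of 16 (0.73). The endoplasmic reticulum chaperone HSPA5 fell from 184.2 to 74.2 FPKM, and in its list 2 of 20 rose and 2 fell (-0.20). CYR61, a matrix-associated early gene, fell from 1112 to 381.5 FPKM. Heat shock genes had none past the rule and a median of -0.15, which became 0.03 when rescaled over protein-coding genes. COL8A1 (10.5 to 0.934 FPKM) and HIPK3 (81.2 to 13.7 FPKM) had some of the largest falls. TGIF2-C20orf24, HNRNPH2, SCHIP1, ERC1, HSPE1-MOB4 and CHMP4A share exons with other genes, and for ERC1 and PSD3 the estimated fragments changed far less than FPKM.

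The cytoplasm split also depends on scaling. After median-of-ratios scaling the genes higher and lower were 337 and 205 at 30 min, 252 and 427 at 3 h, and 539 and 561 at 24 h. Rescaled over protein-coding genes, they were 946 and 158, 1975 and 232, and 1158 and 457, with median changes of 0.27, 0.48 and 0.19 against 0.05, 0.15 and 0.03 as deposited. Median-of-ratios scaling gave 0.04, -0.01 and -0.01. The protein-coding total includes the histone genes, at 48.03% of cytoplasm FPKM without UV and 33.5%, 20.4% and 26.1% after it. A fall in their share by itself raises all other genes under that rescaling. More genes also passed the filter then, 13422, 13082 and 12876 against 12137, 11812 and 11787. Heat shock genes apart, as stated, the cytoplasm list medians given kept their sign under both scalings, but those of G2/M genes came to -0.002 at 30 min and -0.009 at 3 h when rescaled over protein-coding genes.

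**Figure D2:**
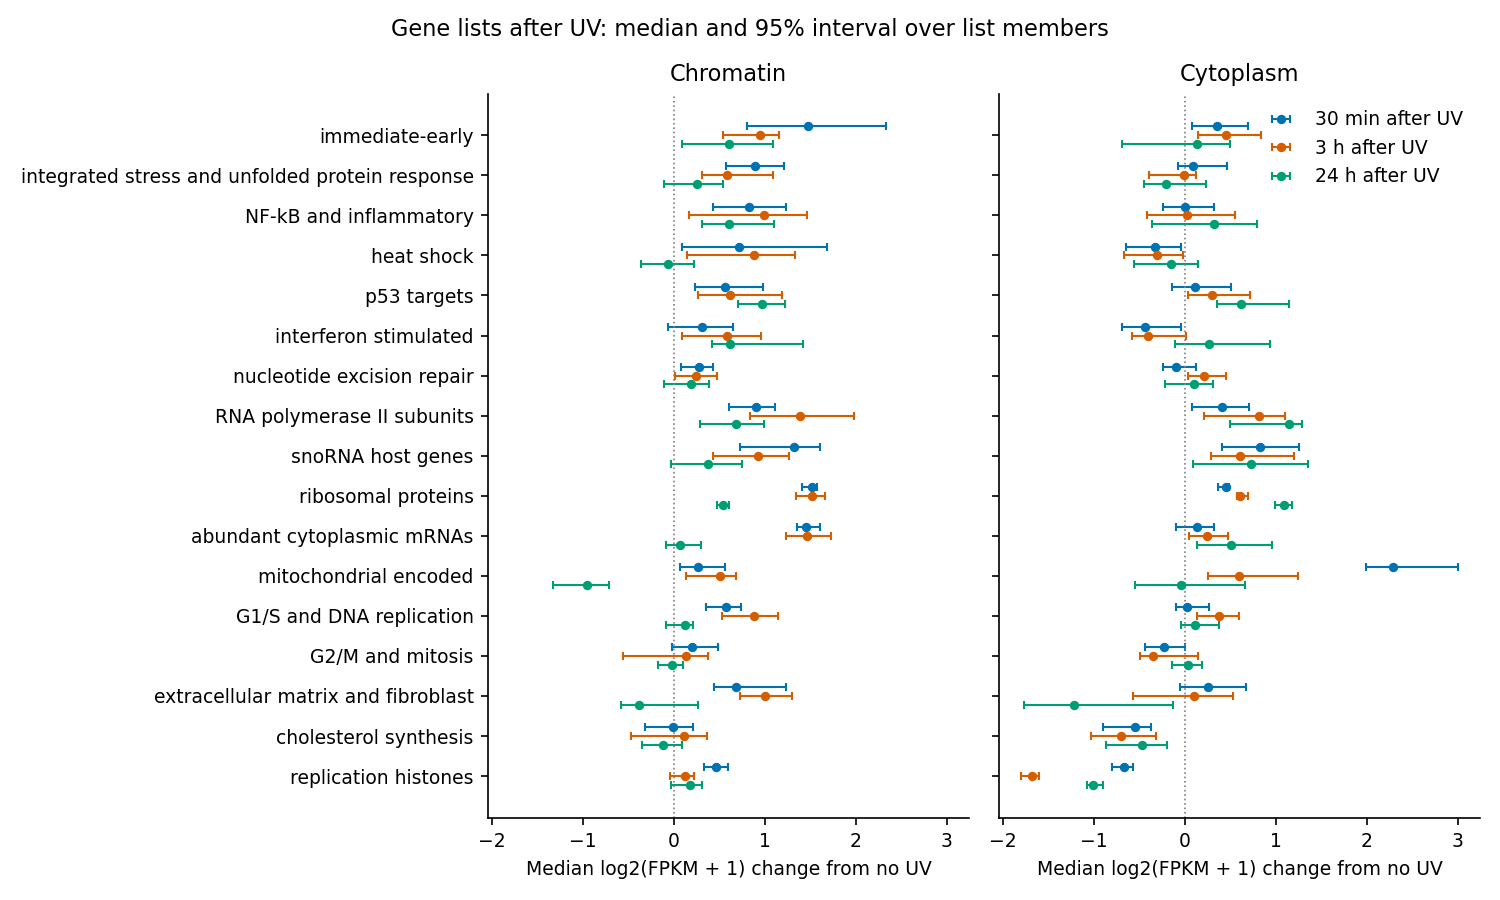
Median change in log2(FPKM + 1) from no UV for 17 gene lists in chromatin and cytoplasm at each recovery time, with points for medians, colours for times and bars for 95% intervals over list members. Mitochondrially encoded RNAs reach 2.29 in cytoplasm at 30 min and replication histones -1.68 at 3 h, while histones on chromatin lie at 0.13 at 3 h, a value that turns negative under other scalings.

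**Figure D3:**
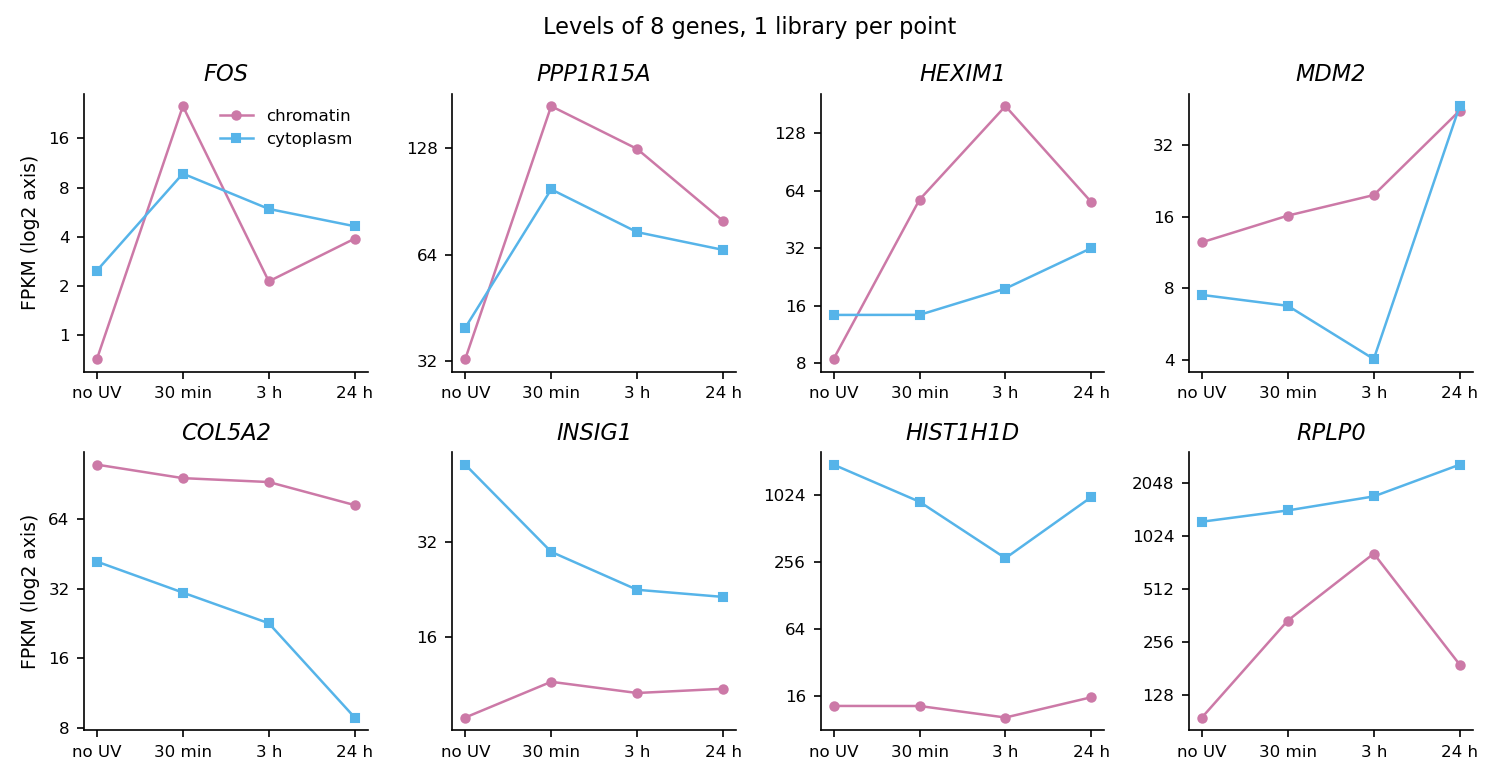
FPKM on a log2 axis of 8 genes at each condition, with circles for chromatin, squares for cytoplasm and 1 library per point. FOS on chromatin peaks at 25.3 at 30 min, HEXIM1 at 177.5 at 3 h and MDM2 at 44.7 at 24 h, and COL5A2 in cytoplasm falls from 41.9 to 8.89.

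A further comparison asked whether the change after UV went with the span of a gene, since a longer template offers more sites for lesions. On chromatin the median change was highest in short protein-coding genes and lowest in long ones, most at 3 h. Genes under 10 kb, such as RPLP0 and HEXIM1, had a median change of 1.13 at 3 h (95% interval 1.09 to 1.16, 2138 genes), and 1247 of them rose while 20 fell. Genes of 10 to 30 kb had a median of 0.70, those of 30 to 100 kb -0.03 and those over 100 kb, such as MID1, -0.58 (-0.60 to -0.54, 2238 genes, of which 37 rose and 454 fell). At 30 min the medians ran from 0.84 to -0.03 and at 24 h from 0.43 to -0.22. A change of scaling moves the medians of all classes together. In cytoplasm the medians under 10 kb and over 100 kb were 0.20 and -0.11 at 30 min, 0.35 and -0.002 at 3 h, and 0.30 and -0.40 at 24 h.

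Across genes, Spearman's rho of change with span was -0.51, -0.69 and -0.42 in chromatin and -0.26, -0.26 and -0.40 in cytoplasm at 30 min, 3 h and 24 h, which are 6 relations in which genes are not independent replicates. In genes at least 2-fold higher in chromatin without UV, chosen after seeing the data, rho in chromatin was -0.17, -0.59 and -0.33. With genes placed by libraries outside the comparison, it was -0.27, -0.63 and -0.33. Exonic length in place of span gave -0.34, -0.37 and -0.19. From 3 h to 24 h, a comparison outside the plan, rho with span was 0.50 in chromatin and -0.20 in cytoplasm.

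**Figure D4:**
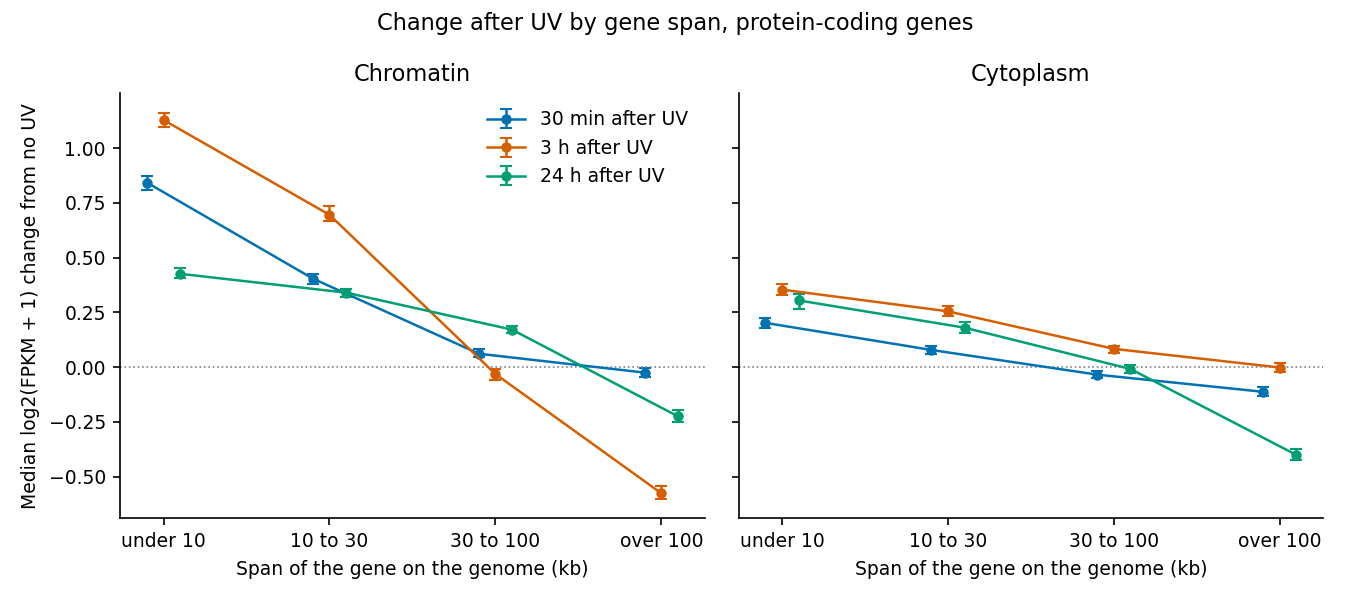
Median change in log2(FPKM + 1) from no UV of protein-coding genes in 4 classes of span (kb), with points for medians and bars for their 95% intervals, in chromatin and cytoplasm. On chromatin at 3 h the median falls from 1.13 under 10 kb to -0.58 over 100 kb.

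The last comparison set the change on chromatin against that in cytoplasm at the same time, with no library shared between them. IER2, FOS, TXNIP and PPP1R15A and the snoRNA hosts SNHG5 and SNHG8 went up in both fractions at 30 min. At 24 h the p53 target BTG2, the phosphatase DUSP6 (1.72 on chromatin and 1.84 in cytoplasm, in log2), the ubiquitin ligase RNF6 and IFIT3 were up in both. At the same time TENM2 (979.4 kb; 20.4 to 4.47 FPKM on chromatin, 13.9 to 2.29 in cytoplasm) and the protein kinase C gene PRKCA (508.1 kb; 25.5 to 7.50 and 14.4 to 4.87 FPKM) went down in both. All of these were chosen after their values were seen, from genes past the rule in both fractions.

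Both fractions rose in 99 genes at 30 min, 207 at 3 h and 105 at 24 h, where independent lists would share 31.9, 101.7 and 28.4. Falls were shared by 15, 51 and 83 genes, against 2.52, 17.9 and 15.5. The counts depend on scaling, most at 3 h, where median-of-ratios scaling gave 88 shared rises (41.6 if independent) and 90 shared falls (41.2). At 30 min it gave 75 and 21, and at 24 h 78 and 112. Opposite directions were found in 20, 27 and 14 genes. Cytoplasmic RNA in the chromatin libraries would by itself make the changes of the fractions alike. The shared counts and the correlations were not recomputed with carry-over subtracted. Across genes measured in both, Spearman's rho was 0.40, 0.35 and 0.39 and Pearson's r 0.37, 0.33 and 0.39, a description in which genes are not replicates. By FPKM, nuclear lncRNAs had no member past the rule in any of the 6 comparisons, with medians of -0.08, -0.20 and 0.22 on chromatin at 30 min, 3 h and 24 h. For MALAT1 on chromatin at 30 min the estimated fragments fell far more than FPKM, so its place in this count is uncertain.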

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

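The 3 tests given for the fall of histone mRNAs in cytoplasm were chosen only after that fall was seen.

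Heat shock genes drew attention because they moved apart between the fractions at 30 min. Their median change was 0.72 on chromatin, at percentile 98.86 of random lists matched on expression, and -0.32 in cytoplasm, at percentile 0.19. The fractions thus differed by 1.04 in log2, a difference that was not tested, since each value rests on 1 pair of libraries. HSPA1A rose on chromatin from 9.10 to 54.2 FPKM, while HSPB1 in cytoplasm went from 399.6 to 253.2 FPKM, short of the 2-fold rule. Matched also on span, the chromatin median lay at percentile 89.8, within the middle 95% of random lists.

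Replication histone mRNAs drew attention for the same reason, with a median of 0.47 on chromatin (percentile 99.55) and -0.67 in cytoplasm (percentile 0) at 30 min. This difference of 1.14 in log2 was not tested either. Matched also on span, the chromatin median lay at percentile 61.3. Both directions were the same under the scalings tried at 30 min.

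Histone mRNAs were lower in cytoplasm at all 3 times, most at 3 h (median -1.68). Scaling alone is argued against, because the median at 3 h was -1.86 after median-of-ratios scaling. The histone median on chromatin at 3 h was 0.13 over 60 genes (95% interval -0.04 to 0.23), or -0.05 and -0.23 under the other scalings. Lists matched also on span had a random median of 0.49, and the histones lay at percentile 1.75 of them. Histone RNA on chromatin was at a median of 0.277% of its cytoplasm level without UV and 1.08% at 3 h. Carried-over cytoplasm could make up such a level, so whether less histone RNA was made cannot be told from the chromatin median. Replication histone mRNAs lack a poly(A) tail, and fewer such RNAs in the library cannot be told apart from a loss in the cells, since the 4 small non-coding RNAs at FPKM of 10 or more had a median of -0.019 (-0.15 to 0.62) and are too few. A loss of histone mRNA with the arrest of DNA synthesis after UV may be the biological side of this, and was not tested.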

How the results depend on the processing

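With 1 library per group, the UV comparisons within a fraction carry no test, a UV effect common to both fractions was not tested, and depth limits single genes near an FPKM of 1. Of 140 values that answer a comparison under another setting, 71 moved and 69 did not, and every Spearman's rho kept its sign. Except where a setting itself admits more or fewer genes, the cause was not tested. Rescaling list medians over protein-coding genes, the settings for genes shared by the fractions, removal of genes with overlapping exons, subtraction of carry-over, restriction to genes higher in chromatin by either placing, and the fraction fit without 30 min and 3 h were chosen after seeing the data.

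Genes at least 2-fold changed numbered 2460, 5681 and 2303 in chromatin at 30 min, 3 h and 24 h, and 532, 768 and 1116 in cytoplasm. In the same order, with only counts beyond 1.5 times of these given, a pseudocount of 5 gave 641, 2008, 335, 132, 282 and 432. A 1.5-fold rule gave 6644, 10666, 6145, 2254, 3029 and 3579, and a 3-fold rule 433, 1735, 503, 102, 134 and 168. A pseudocount of 0.1 gave 4489 at 30 min and 4145 at 24 h in chromatin, and 1229, 1396 and 1892 in cytoplasm. Rescaling over protein-coding genes, which let more genes past the filter, gave 6281, 11409 and 7197 in chromatin, and 1104 at 30 min and 2207 at 3 h in cytoplasm. Protein-coding genes alone gave 1464, 3330 and 1004 in chromatin and 309 at 30 min in cytoplasm. An FPKM filter of 5 gave 1076 in chromatin at 24 h and 296 in cytoplasm at 30 min. Asking that the counting interval exclude 1 gave 1304 in chromatin at 24 h. Without overlapping exons there were 486 at 3 h and 730 at 24 h in cytoplasm.

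Spearman's correlation with span of the change from no UV was negative under each setting. An FPKM filter of 5 gave -0.55 and -0.72 in chromatin and -0.29 and -0.29 in cytoplasm at 30 min and 3 h. Exonic length in place of span gave -0.34, -0.37 and -0.19 in chromatin at the 3 times, and -0.21 at 30 min and -0.35 at 24 h in cytoplasm. In genes higher in chromatin without UV it was -0.17, -0.59 and -0.33 in chromatin and -0.19, -0.16 and -0.43 in cytoplasm. With genes placed by libraries outside the comparison it was -0.27, -0.63 and -0.33, and -0.21, -0.13 and -0.30. Without overlapping exons it was -0.49 at 30 min and -0.45 at 24 h in chromatin, and -0.24, -0.24 and -0.42 in cytoplasm. With carry-over subtracted it was -0.49 in chromatin at 30 min. Spearman's correlation between the fractions was 0.45 at 30 min and 0.39 at 3 h with an FPKM filter of 5, and 0.41 at 24 h without overlapping exons.

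Between chromatin and cytoplasm, the 9703 genes became 4431 with a pseudocount of 5, 6320 with an FPKM filter of 5, 18954 rescaled over protein-coding genes and 5580 in protein-coding genes alone. The rescaled count comes from 24855 genes tested, against 17417 as deposited. Leaving out each condition in turn gave 9261 to 9827, and the fit without the block 9681. Of 578 list medians under another setting, 496 stayed within their interval and 76 moved: 14 down by up to 0.21 with median-of-ratios scaling, 1 down with an FPKM filter of 5, 2 up with a pseudocount of 0.1, and 39 up and 20 down rescaled over protein-coding genes. The other 6 are medians beyond the middle 95% of random lists that changed sign. Between the fractions, NF-kB and inflammatory genes went from -0.60 to 0.33 with the FPKM filter of 5, which leaves out less abundant members, and to 0.84 rescaled over protein-coding genes. That rescaling also took integrated stress genes to 0.57 and cholesterol synthesis genes to 0.31, and heat shock genes in cytoplasm to 0.071 at 3 h and 0.034 at 24 h. Counting medians within the middle 95% too, 12 of 125 medians after UV changed sign with median-of-ratios scaling, 18 rescaled over protein-coding genes and 4 of 120 with the FPKM filter of 5. Between the fractions 11 of 21 did so rescaled over protein-coding genes, 1 of 20 with the filter and 0 with median-of-ratios scaling. Of 24 counts of genes shared by the fractions, 14 moved by more than 1.5 times. Of 1292 values of named genes, 595 moved and 697 did not.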

Other observations

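Some genes, chosen after their values were seen, changed in the same direction in both fractions. TXNIP, which binds thioredoxin and limits glucose uptake, rose on chromatin from 1.07 FPKM to 22.3, 6.14 and 6.43 at 30 min, 3 h and 24 h, and in cytoplasm from 1.41 to 6.53, 7.68 and 5.29. RNF6, a ubiquitin ligase, rose on chromatin from 5.53 to 70.7 FPKM at 3 h and 36.2 at 24 h, and in cytoplasm from 5.73 to 19.3 and 31.9. MARCKSL1, an actin-binding protein, rose from 0.96 to 10.7 FPKM on chromatin and from 15.98 to 68.4 in cytoplasm at 24 h. PLAC8 fell on chromatin from 74.8 to 26.5 FPKM at 30 min and 19.6 at 3 h, and in cytoplasm from 163.4 to 65.4 and 66.1. PPP2R2B, a regulatory subunit of protein phosphatase 2A, fell at all 3 times in both fractions, at 24 h from 17.9 to 5.05 FPKM on chromatin and from 18.8 to 5.08 in cytoplasm.

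Of the tests that follow, those on cytoplasmic RNA in the chromatin libraries, on carry-over, on MALAT1 and on other splits were chosen only after the result was seen. So were the requirement that a whole interval lie below -0.1 and the use of libraries outside the comparison to place genes. Intervals of rho take genes as independent, which they are not.

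On chromatin the change after UV was lower the longer the gene, most at 3 h. Cytoplasmic RNA in the chromatin libraries as the whole cause is argued against at 3 h and, narrowly, at 24 h, because in genes at least 2-fold higher in chromatin in libraries outside the comparison rho of change with span was -0.63 (95% interval -0.65 to -0.61) and -0.33 (-0.367 to -0.301). Short genes at 24 h, placed by the 3 h libraries, had medians of 0.37 mainly on chromatin and 0.42 mainly in cytoplasm. With genes placed by the libraries without UV, rho at 24 h was also -0.33. Short genes higher in chromatin by that placing had a median of only 0.05 (252 genes), so their rise at 24 h depends on the placing. At 30 min cytoplasmic RNA as the cause cannot be told apart, because that rho was -0.27 (-0.30 to -0.23), or -0.17 with genes placed by the libraries without UV, against -0.51 over all genes. Bias by length of the mature transcript is argued against at 3 h, because rho at fixed exonic length was -0.62 over 11323 genes. Lower RNA output along the gene, growing with its span, may be part of it, but this cannot be told apart here, because within genes over 100 kb rho was -0.11 at 3 h with an interval (-0.15 to -0.07) reaching past -0.1, 0.05 at 30 min and -0.43 at 24 h.

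Ribosomal protein and other mRNAs abundant in cytoplasm were higher on chromatin at 30 min and 3 h. Unselective carry-over of cytoplasm would add the same percentage points to the chromatin to cytoplasm ratio of every mRNA. At 30 min the median ratio gained 0.44 points for histone mRNAs (0.277% to 0.718%) and 8.35 for abundant mRNAs (7.13% to 15.5%). Unselective carry-over is thus argued against. In relative terms the histone ratio rose no less, so carry-over that takes each class in its own proportion is not argued against. The smaller share of MALAT1 left room for a common rise of 0.16 in log2 by its share of FPKM and 0.17 by its estimated fragments, against medians of 1.52 and 1.45. Higher output of short genes whatever their place is argued against as the whole cause at 30 min, because short genes mainly in cytoplasm had a median of 1.02 and those mainly on chromatin 0.33, a gap of 0.68 (0.55 to 0.83). At 3 h these medians were 1.27 and 0.94, a gap of 0.33, so it cannot be told apart at that time. Carry-over of particular RNA classes, such as RNA on ribosomes or membranes, could still differ between preparations and stays open, as does retention of mature mRNA in the nucleus, and neither was tested.

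For genes differing between chromatin and cytoplasm, the conditions pair the libraries, and 8 splits of the 8 libraries into 4 and 4 part every pair. The real split called 9703 genes and the highest of the others 0, so 1 of the 8 called as many. The other splits swap the fractions in some conditions, so a large fraction difference enters their error and holds calls down. Their lack of calls is thus built in, and the comparison with them decides nothing. The 8 splits are also too few for a share under 0.05.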
